A study of Arabidopsis thaliana with 36 samples.

How the data were processed

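RNA from whole 12-day-old seedlings of WT and 4 double mutants was sequenced from the 3' end after 6 h of treatment, 36 libraries in 12 groups of 3 repeats, per the labels. Per the submitters' processing notes the tools were Trim Galore 0.2.8, TopHat2 2.1.1, SAMtools and HTSeq 0.6.0. The genome build, the annotation release and the strand setting of HTSeq were not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited files hold whole-number HTSeq counts for 58699 transcript models of 37336 loci. A read shared by 2 or more models of a gene was set aside as ambiguous, which took 39.9 to 42.8% of the assigned and ambiguous reads of a library. A further 2.69 to 6.32% of reads fell on no feature. These summary lines stayed out of library sizes and tests. Genes with several models are therefore undercounted, and 91.1 to 93.6% of the counts came from the 26319 loci with 1 model. Values of near-identical paralogs (BIP1 and BIP2, the XTH12 group, the HSP17.6 genes, LHCB1 copies, RPL4A and RPL4D) are uncertain.

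Counts were summed per locus. Gene symbols were taken from the TAIR10.1 gene table by locus tag, in which 37051 of the 37336 loci were found, and no coordinates were used in the comparisons. Genes were kept with edgeR's filterByExpr (minimum count 10), leaving 10480 genes, 8876 of them with 1 model. All 36 libraries were fitted together with edgeR 4.0.16 (TMM factors, quasi-likelihood F-test, 24 residual degrees of freedom) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. The 22 comparisons were each inducer against mock in WT, the inducers against each other, Tm against mock in each mutant, the difference of the Tm responses of 2 genotypes, and genotypes against each other under mock. The labels do not say that repeats were grown separately, so p-values measure only the spread between these samples, which may be technical. No 2 libraries of a group held identical counts, and the chi-square over its degrees of freedom of repeat pairs ran from 1.50 to 12.1.

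The 21 gene lists, the comparisons, the tests and the rule for named genes were set before the data were examined. List members were written from memory as locus tags and were not checked against a source. The heat shock list, drawn as cytosolic, also holds organellar and ER members. UPR regulators were tested again without BZIP17, BZIP28 and BZIP60 after the data were seen. Of 353 list members 240 were tested, and most of those left out have several models. Lists were tested with camera in limma 3.58.1 (preset correlation 0.01), adjusted over the 21 lists of a comparison. 196 list tests of 22 comparisons were called, and 75 of these were not called with an estimated correlation. The report describes mainly lists called with both, with their preset p. The rule named the 6 largest rises and 4 largest falls with at least 5 CPM and no overlap between the 3 and 3 libraries (10% by chance), the 3 lowest p of each called list, the genes named by the genotypes, and 12 fixed UPR genes for differences between Tm responses. Not all genes so named are printed. Of those 12, BIP2, BIP3, ERDJ3A and PDIL2-1 had too few counts to be tested. Simulations with 200 changed genes checked the fit. At log2 changes of 1 and -1 it recovered 84 and 66% for Tm in WT and 46 and 56% for bzip28/60 against WT. At 2 and -2 the latter had 92 and 98%. False calls were 6.52 and 4.58% of calls. The wider WT Tm spread was not simulated.

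Alternatives were relative log expression factors, library size alone, no filter on low counts, DESeq2 1.42.0, only the libraries of a comparison fitted, organelle genes left out, the repeat number as a block, and each library left out in turn. Transcript models as deposited, genes with 1 model only, and a spread per group (limma-voom) were added after seeing the data. Library size alone moved the median of all genes by more than 0.1 in 2 of 22 comparisons, by 0.109 for bzip17/28 against WT under mock and by 0.103 for Tm in bzip17/60. Relative log expression factors did so in 0. Genotypes differed in the share of reads on no feature, 3.68 to 4.84% in the WT groups and 2.77 to 3.19% in the mutant groups. The labels give no library batch, so a batch and the genotype cannot be told apart for WT against mutants.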

Results

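Transcript abundance was measured in 12-day-old whole Arabidopsis thaliana seedlings by 3'-end mRNA sequencing after 6 h in water with an inducer of the unfolded protein response (UPR) or with the solvent alone (mock). The UPR is the transcriptional response to misfolded proteins in the endoplasmic reticulum (ER). Wild type (WT) received mock, tunicamycin (Tm, 5 µg/ml, a blocker of N-glycosylation), dithiothreitol (DTT, 2 mM, a reductant of disulfide bonds) or L-azetidine-2-carboxylic acid (AZC, 5 mM, a proline analogue that enters proteins). The double mutants bzip17/28, bzip28/60, bzip17/60 and s1p/s2p received mock or Tm. bZIP17 and bZIP28 are membrane-anchored transcription factors released by the Golgi proteases S1P and S2P, and bZIP60 is the transcription factor made after IRE1 splices its mRNA. Each of the 12 groups held 3 libraries, 36 in all, with 1278322 to 2810235 assigned counts per library (median 2011039). 10480 genes were tested in 22 comparisons. Values after a gene symbol are log2 fold changes ± standard error with n = 3 libraries per group and edgeR's Benjamini-Hochberg adjusted p, and values after a gene list are the number of measured members that passed, their mean log2 fold change and camera's adjusted p. Genes said to have risen or fallen, or to be higher or lower, passed at an adjusted p under 0.05. Where no second count stands beside a list, the count adjusted over the list alone was the same. Ratios against 1 to 3 counts carry their 95% counting interval, and ratios against 0 counts are lower bounds from a floor of 3 counts over the group, both for counting error only.

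The genes named by the genotypes were read first. BZIP17 (AT2G40950) had 0 to 3 counts per library in bzip17/28 and bzip17/60, against 5 to 21 in WT mock. BZIP28 (AT3G10800) had 0 to 1 counts per library in bzip17/28 and 23 to 30 in bzip28/60 mock, where its level was 11.3 ± 2.80 CPM against 24.6 ± 4.00 CPM in WT mock (SD, n = 3, log2 fold change -1.12 ± 0.26), a call lost without 1 library for BZIP28 (adjusted p up to 0.0541 without bzip28/60 mock 1 or 3). BZIP60 (AT1G42990) stood at 33.1 ± 3.55 CPM (TMM-scaled, SD, n = 3) in bzip28/60 mock and 32.0 ± 1.17 CPM in bzip28/60 Tm. In bzip17/60 it stood at 29.9 ± 4.56 and 36.1 ± 2.30 CPM. The other genotypes carried BZIP60 at 125 ± 15.0 CPM (WT mock) to 1783 ± 139 CPM (bzip17/28 Tm). S1P and S2P had 0 to 1 counts in every library of every genotype, so these counts could not check the s1p/s2p label. A 3'-end read outside an insertion does not check a mutant either, and the remaining BZIP28 and BZIP60 counts in bzip28/60 and bzip17/60 were taken as measured.

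**Figure D1:**
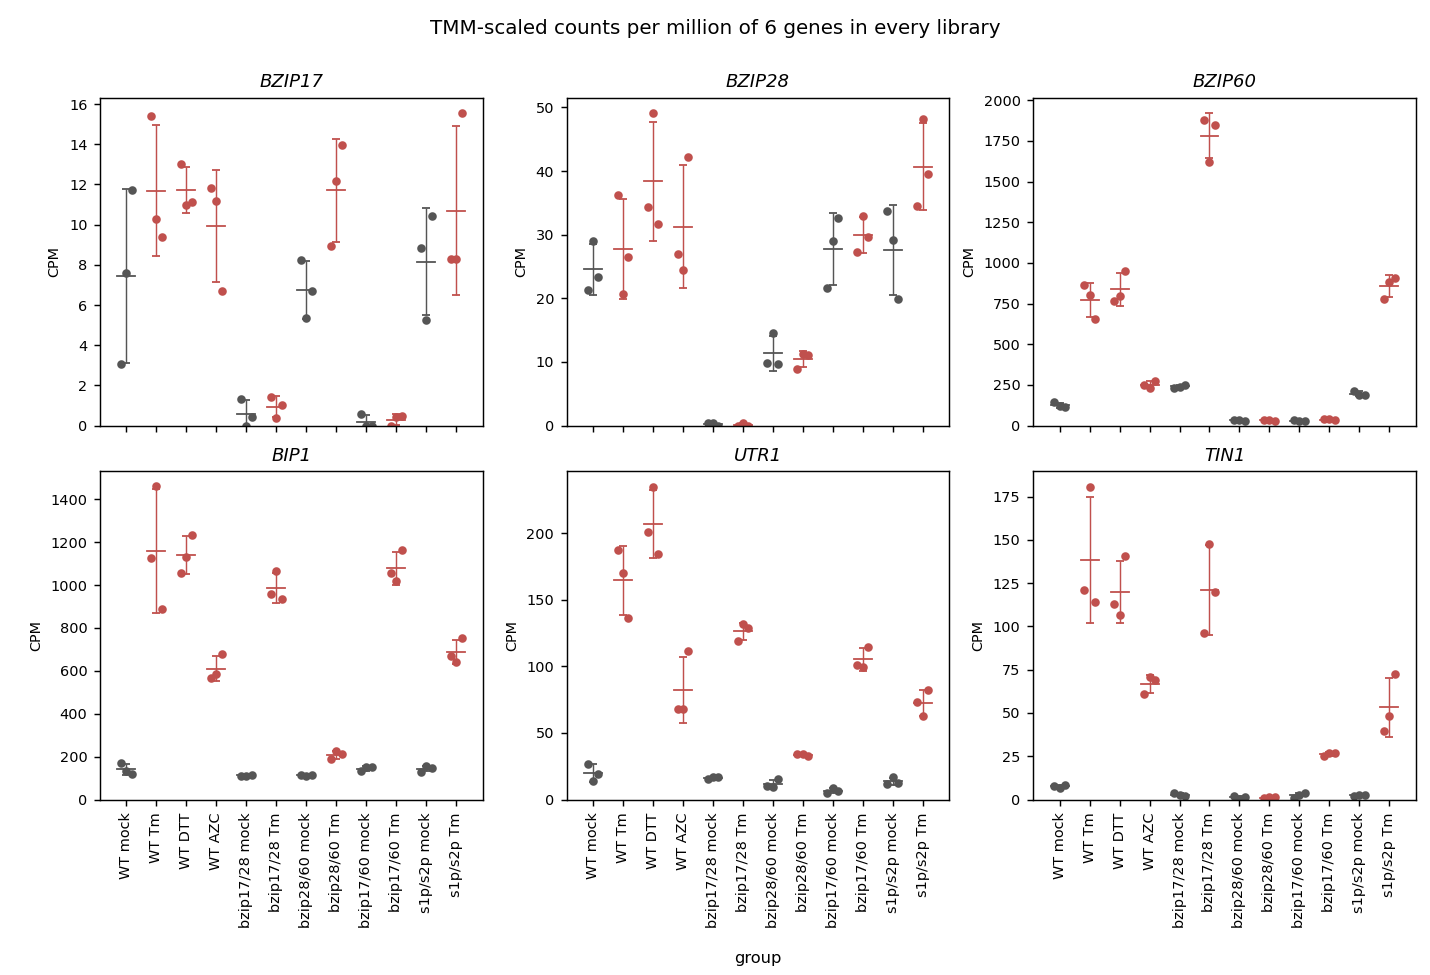
TMM-scaled CPM (y axis, linear, from 0) of BZIP17, BZIP28, BZIP60, BIP1, UTR1 and TIN1 in the 36 libraries by group (x axis), with a point per library, a line at the mean and bars of 1 SD (n = 3). BIP1 rose from 141 ± 24.9 to 1159 ± 289 CPM with Tm in WT and from 144 ± 10.7 to 1079 ± 76.1 CPM in bzip17/60. In bzip28/60 the means were 113 and 209 CPM.

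**Figure D2:**
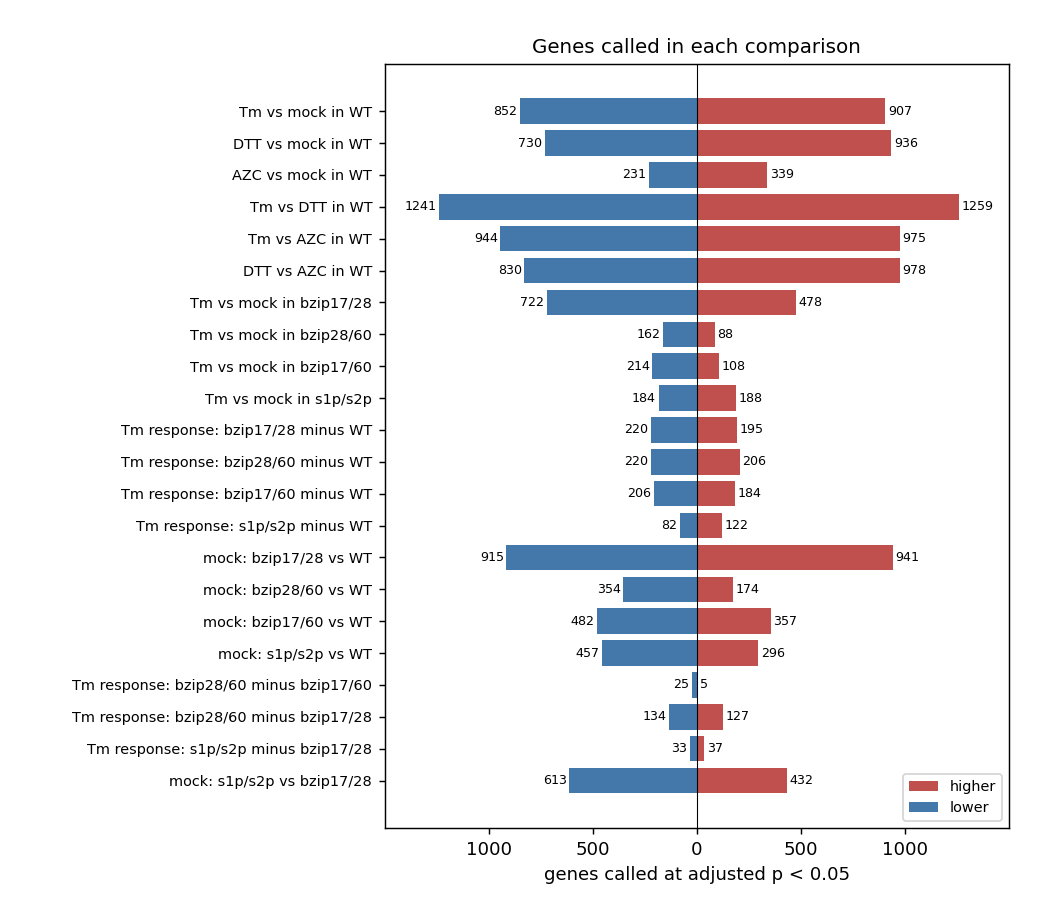
Genes called at an adjusted p under 0.05 in the 22 comparisons (y axis), higher to the right and lower to the left (x axis). Tm in WT had 907 higher and 852 lower genes and Tm in bzip28/60 had 88 and 162. With only own libraries fitted the order reversed, at 262 and 732.

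Tm against mock in WT asked which genes respond to blocked N-glycosylation. 1759 genes changed, 907 higher and 852 lower with Tm. The ER chaperone gene BIP1 (AT5G28540, 3.04 ± 0.15, adjusted p = 2.09e-21), which shares reads with the near-identical BIP2, rose from 141 ± 24.9 to 1159 ± 289 CPM (SD, n = 3). The lectin chaperone CNX1 (AT5G61790, 2.73 ± 0.15, adjusted p = 1.61e-19) and the disulfide isomerase PDIL1-2 (AT1G77510, 3.24 ± 0.18, adjusted p = 1.66e-19) rose beside it. Among the 6 largest rises were the COPII coat genes SAR1A (AT1G09180, 31.3-fold higher, 10.3 to 155) and SEC31A (AT1G18830, 4.24 ± 0.34), the ADP-ribosylation factor ARFA1D (AT1G70490, 4.63 ± 0.31), the tunicamycin-induced gene TIN1 (AT5G64510, 4.14 ± 0.25), the translocon subunit SEC61B2 (AT3G60540, 3.94 ± 0.72) and AT4G21730 (5.30 ± 0.55). In the ER protein folding list 14 of 21 rose (mean 1.63, adjusted p = 6.67e-54, 15 rose and 1 fell adjusted over the list alone). In ER-associated degradation 6 of 9 rose (mean 0.89, adjusted p = 3.05e-09). In ER translocation and signal peptidase 8 of 13 rose (mean 1.16, adjusted p = 6.31e-06). Examples were HRD3A (AT1G18260, 1.56 ± 0.17) of the degradation ubiquitin ligase, the lectin OS9 (AT5G35080, 2.29 ± 0.25), the derlin DER2.1 (AT4G21810, 1.53 ± 0.14), SEC61G2 (AT5G50460, 1.57 ± 0.12) and SPC22A (AT3G05230, 2.46 ± 0.34). In N-glycosylation 3 of 9 rose and 1 fell (mean 0.86, adjusted p = 1.46e-05), led by the nucleotide sugar transporters UTR1 (AT2G02810, 3.03 ± 0.20) and UTR3 (AT1G14360, 2.97 ± 0.26) and by GPT (AT2G41490, 1.90 ± 0.26, adjusted p = 4.28e-07), the enzyme that Tm inhibits. In ER to Golgi transport 6 of 7 rose (mean 1.92, adjusted p = 8.66e-15). In UPR regulators 4 of 8 rose and 1 fell (mean 1.54, adjusted p = 3.13e-14). SAR1B (AT1G56330, 1.51 ± 0.14), BZIP60 (AT1G42990, 2.63 ± 0.13) and the Bax inhibitor BI1 (AT5G47120, 1.76 ± 0.13) rose.

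Lower with Tm in WT were the small heat shock genes HSP15.7 (AT5G37670, 13.9-fold lower, 3.53 to 119.8) and HSP17.6A (AT5G12030, -3.55 ± 0.75), the defensin PDF1.4 (AT1G19610, 12.5-fold lower, 4.01 to 63.3) and the plastid photosystem II gene ATCG00270 (12.1-fold lower, 3.04 to 105). In the heat shock list 15 of 24 fell (mean -1.58, adjusted p = 4.97e-11), among them HSP23.5 (AT5G51440, -2.19 ± 0.35), HSP70-4 (AT3G12580, -1.78 ± 0.26) and HSP101 (AT1G74310, -1.77 ± 0.29). In glutathione transferases 3 of 12 fell (mean -1.01, adjusted p = 0.00202 or 0.123 with an estimated correlation, 4 fell adjusted over the list alone), among them GSTU19 (AT1G78380, -0.82 ± 0.13). The other 13 lists had adjusted p of 0.0752 or more, including 26S proteasome, where 1 of 12 rose and 2 fell (mean 0.05, adjusted p = 0.891, 3 rose and 2 fell adjusted over the list alone), and proline metabolism, where 0 of 3 passed (mean -0.38, adjusted p = 0.89, 1 rose and 2 fell adjusted over the list alone). BZIP17 and BZIP28 had log2 values of 0.61 ± 0.38 and 0.18 ± 0.25, which did not pass. The 3 WT Tm libraries varied more than those of any other group, with a biological coefficient of variation of 28.2% against 5.57 to 14.3%, and the count of changed genes was 262 with only these libraries fitted, 535 with a spread per group and 993 without WT Tm 2. The call was lost for HSP15.7, HSP17.6A, PDF1.4, ATCG00270 and HSP23.5 with a spread per group and for GSTU19 with only these libraries fitted.

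DTT against mock in WT asked which genes respond to reduced disulfide bonds. 1666 genes changed, 936 higher and 730 lower. BIP1 (3.01 ± 0.15, adjusted p = 1.68e-21), CNX1 (2.75 ± 0.15, adjusted p = 9.76e-20) and the J-domain cochaperone ERDJ3B (AT3G62600, 2.69 ± 0.16, adjusted p = 4.67e-19) rose. Among the ER protein folding list genes 15 of 21 rose (mean 1.67, adjusted p = 2.08e-44). The other secretory lists rose too: in ER-associated degradation 7 of 9 rose (mean 0.98, adjusted p = 8.57e-10). In translocation and signal peptidase 5 of 13 rose (mean 1.00, adjusted p = 4.32e-06). Among N-glycosylation genes 3 of 9 rose (mean 0.92, adjusted p = 1.1e-05). Among ER to Golgi transport genes 4 of 7 rose (mean 2.03, adjusted p = 2.27e-13, 5 rose adjusted over the list alone). In UPR regulators 5 of 8 rose (mean 1.83, adjusted p = 2.52e-18). Among these were SEC31A (5.93 ± 0.29), SAR1A (32.6-fold higher, 10.8 to 161), TIN1 (3.93 ± 0.25), BZIP60 (2.75 ± 0.13), UTR1 (3.37 ± 0.20) and BI1 (2.27 ± 0.13). The largest rises also took in the cytochrome P450 CYP82C2 (AT4G31970, 81.0-fold higher, 22.0 to 675), which makes indole defence compounds, and AT4G22030 (at least 9.78-fold higher), AT3G49540 (at least 9.06-fold higher), AT3G21305 (71.7-fold higher, 12.4 to 2875) and AT4G21730 (5.92 ± 0.51).

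Stress and defence lists rose with DTT as well. In oxidative and mitochondrial stress 8 of 11 rose (mean 1.44, adjusted p = 1.99e-10), with the zinc finger factor ZAT12 (AT5G59820, 2.26 ± 0.21), the kinase OXI1 (AT3G25250, 2.99 ± 0.36) and the alternative oxidase AOX1A (AT3G22370, 1.52 ± 0.20). In glutathione transferases 8 of 12 rose and 1 fell (mean 1.26, adjusted p = 6.95e-06). An example was GSTU12 (AT1G69920, 4.21 ± 0.36). In immune response 7 of 12 rose (mean 1.45, adjusted p = 3.03e-07, 8 rose and 1 fell adjusted over the list alone). Examples were NHL10 (AT2G35980, 3.83 ± 0.33) and WRKY33 (AT2G38470, 2.51 ± 0.33). In autophagy and cell death 2 of 9 rose and 1 fell (mean 0.56, adjusted p = 0.0159, 6 rose and 1 fell adjusted over the list alone), where DMP1 (AT3G21520, 2.45 ± 0.24) and ATG8H (AT3G06420, 1.06 ± 0.23) rose and the vacuolar protease GVPE (AT4G32940, -0.67 ± 0.14) fell. Root genes were lower: in root markers 9 of 10 fell (mean -2.78, adjusted p = 8.57e-10). In root hair 5 of 7 fell (mean -3.03, adjusted p = 3.93e-05, 7 fell adjusted over the list alone). They included the phosphate transporter PHT1;1 (AT5G43350, -3.92 ± 0.31), the Casparian strip gene CASP1 (AT2G36100, -2.82 ± 0.48) and the root hair wall genes PRP3 (AT3G62680, -3.35 ± 0.60) and EXPA7 (AT1G12560, -2.84 ± 0.56). The largest falls were AT5G54370 (at least 10.7-fold lower) and AT4G22520 (41.4-fold lower, 11.1 to 347) and the peroxidase AT3G49960 (-4.67 ± 0.45). In secreted cell wall proteins 1 of 15 rose and 6 fell (mean -0.52, adjusted p = 0.00332 or 0.0681 with an estimated correlation, 1 rose and 9 fell adjusted over the list alone). 26S proteasome, abscisic acid and osmotic stress and photosynthesis were called with the preset correlation only. The call was lost for AT4G22030 with DESeq2.

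AZC against mock in WT asked which genes respond to a proline analogue. 570 genes changed, 339 higher and 231 lower. Heat shock genes led. Among the heat shock list genes 23 of 24 rose (mean 4.33, adjusted p = 3.33e-160, 24 rose adjusted over the list alone). Among them the disaggregase HSP101 (4.85 ± 0.19, adjusted p = 2.85e-25) rose from 26.3 ± 8.46 to 767 ± 194 CPM (SD, n = 3). The small heat shock genes HSP17.6A (5.82 ± 0.41), HSP17.6C (AT1G53540, 5.77 ± 0.34), HSP22 (AT4G10250, 5.73 ± 0.42) and HSP23.6 (AT4G25200, 5.66 ± 0.28) and the cochaperone HOP3 (AT4G12400, at least 13.6-fold higher) rose as well. The class I HSP17.6 genes are similar in sequence and their separate values are uncertain. ER genes rose by less: in ER protein folding 13 of 21 rose and 1 fell (mean 0.95, adjusted p = 3.63e-25). Examples were BIP1 (2.11 ± 0.14), CNX1 (1.81 ± 0.15) and ERDJ3B (1.77 ± 0.16). In UPR regulators 3 of 8 rose (mean 0.93, adjusted p = 4.35e-08). In ER-associated degradation 3 of 9 rose (mean 0.34, adjusted p = 0.00957, 4 rose adjusted over the list alone, adjusted p up to 0.0783 without WT AZC 3). UTR1 (2.03 ± 0.20) rose. In sulfur assimilation 8 of 11 rose (mean 1.38, adjusted p = 1.08e-10), with the low-sulfur responsive LSU2 (AT5G24660, 2.49 ± 0.31), the hydroxymethyltransferase SHM7 (AT1G36370, 1.72 ± 0.26) and the reductase APR2 (AT1G62180, 0.98 ± 0.20). Among oxidative and mitochondrial stress genes 5 of 11 rose (mean 0.97, adjusted p = 5.93e-07). An example was CYP81D8 (AT4G37370, 2.44 ± 0.33). In root hair 4 of 7 fell (mean -2.88, adjusted p = 3.34e-07, 6 fell adjusted over the list alone). Examples were PRP3 (-3.43 ± 0.60) and EXPA7 (-2.92 ± 0.56). In root markers 3 of 10 fell (mean -0.55, adjusted p = 0.0475 or 0.188 with an estimated correlation, 1 rose and 3 fell adjusted over the list alone, adjusted p up to 0.114 without WT AZC 1, 2 or 3 or WT mock 2). Other large falls were CASP4 (AT5G06200, 26.4-fold lower, 4.35 to 1082) and AT3G49960 (-3.43 ± 0.37). The count of changed genes was 368 without WT mock 3. The call was lost for the root markers list with only these libraries fitted or library size alone or no filter on low counts.

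**Figure D3:**
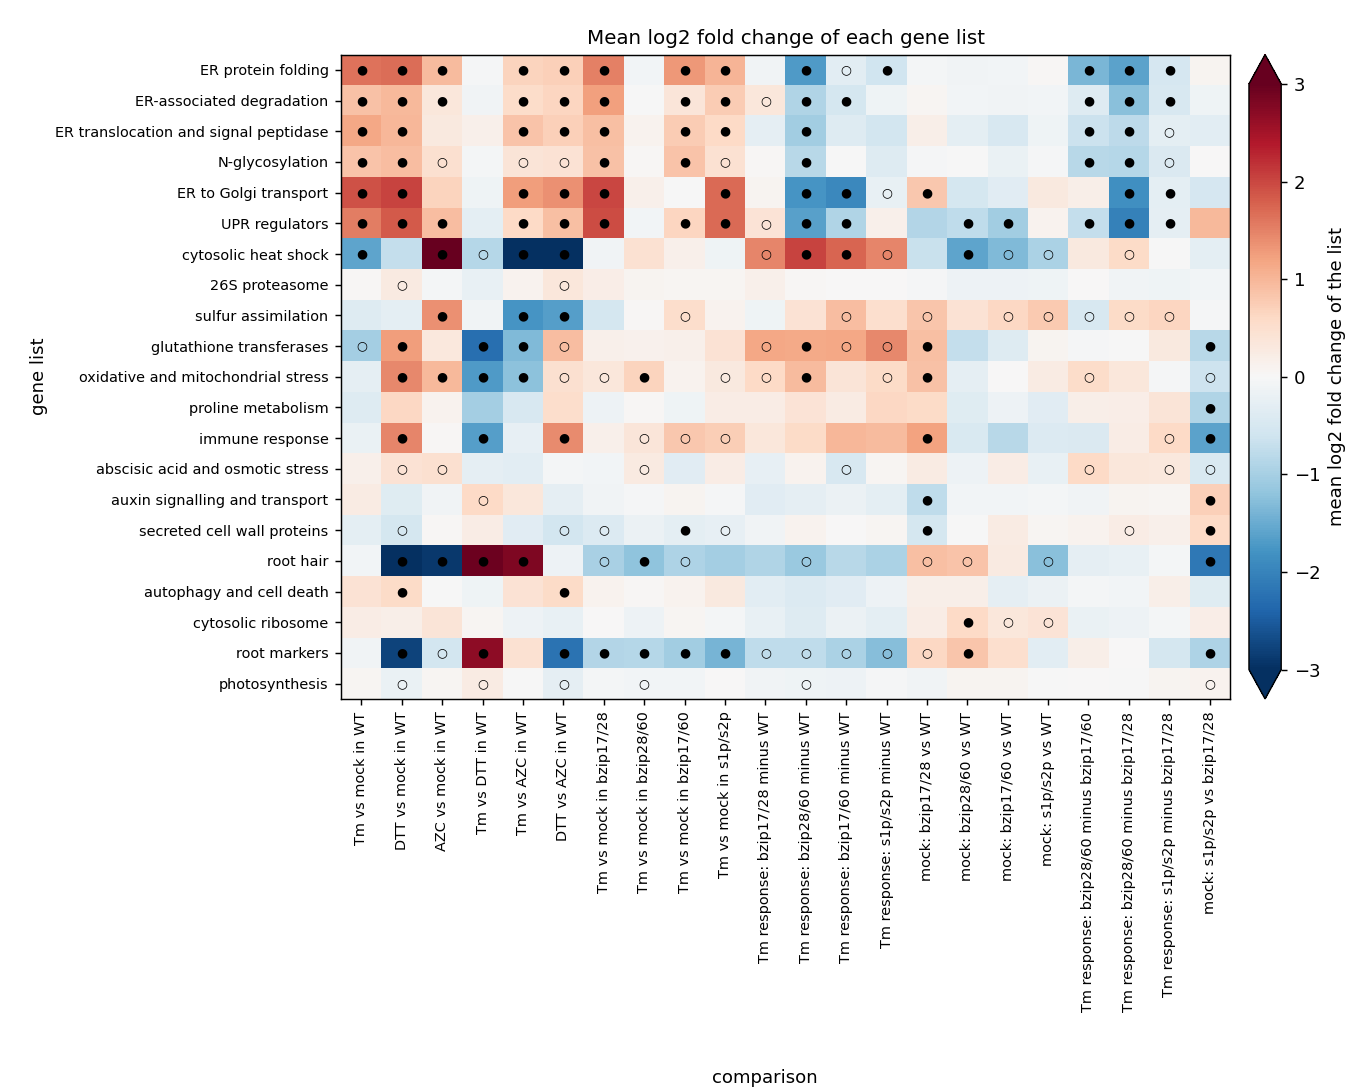
Mean log2 fold change (colour, ending at -3 and 3) of the 21 gene lists (y axis) in the 22 comparisons (x axis). Filled circles mark lists called by camera with the preset and the estimated correlation, and open circles those called with the preset correlation only. The heat shock list had a mean of 4.33 with AZC and -1.58 with Tm.

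The inducers were set against each other directly. Between Tm and DTT 2500 genes differed, 1259 higher with Tm and 1241 lower. None of the 6 secretory lists was called. In ER protein folding 3 of 21 were higher with Tm and 3 were lower (mean -0.04, adjusted p = 0.994). Root genes were higher with Tm: in root markers 8 of 10 were higher (mean 2.68, adjusted p = 4.81e-08). In root hair 6 of 7 were higher (mean 2.94, adjusted p = 0.000272, 7 were higher adjusted over the list alone). Examples were PHT1;1 (3.80 ± 0.31), CASP1 (3.28 ± 0.45) and PRP3 (3.15 ± 0.63). Defence and stress genes were lower with Tm: in glutathione transferases 1 of 12 was higher and 7 were lower (mean -2.27, adjusted p = 3.61e-11, 1 was higher and 9 were lower adjusted over the list alone). Within oxidative and mitochondrial stress 10 of 11 were lower (mean -1.71, adjusted p = 3.61e-11). In immune response 6 of 12 were lower (mean -1.66, adjusted p = 6.39e-06, 7 were lower adjusted over the list alone). CYP82C2 (at least 48.3-fold lower), NATA1 (AT2G39030, 131-fold lower, 23.2 to 5229), GSTU12 (-5.47 ± 0.43), OXI1 (-3.81 ± 0.42), PAD3 (AT3G26830, -4.95 ± 0.65) and NHL10 (-3.27 ± 0.31) were among them, NATA1 being an ornithine acetyltransferase and PAD3 the last enzyme of camalexin synthesis. The call was lost for NATA1 and PAD3 with a spread per group. The count was 811 with only these libraries fitted and 1084 with a spread per group.

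Between Tm and AZC 1919 genes differed, 975 higher with Tm and 944 lower. In heat shock 24 of 24 were lower (mean -5.90, adjusted p = 3.06e-130). Examples were HSP17.6A (-9.37 ± 0.56), HSP22 (434-fold lower, 77.5 to 17178) and HSP101 (-6.61 ± 0.23). In sulfur assimilation 9 of 11 were lower (mean -1.78, adjusted p = 4.5e-10, 10 were lower adjusted over the list alone). In glutathione transferases 7 of 12 were lower (mean -1.33, adjusted p = 4.79e-05, 8 were lower adjusted over the list alone). Of the oxidative and mitochondrial stress genes 9 of 11 were lower (mean -1.24, adjusted p = 4.64e-06). Secretory lists were higher with Tm: in ER protein folding 11 of 21 were higher (mean 0.68, adjusted p = 4.11e-11, 12 were higher adjusted over the list alone). In ER-associated degradation 5 of 9 were higher and 1 was lower (mean 0.55, adjusted p = 0.000996, 6 were higher and 1 was lower adjusted over the list alone). Within ER to Golgi transport 5 of 7 were higher (mean 1.26, adjusted p = 1.02e-09, 6 were higher adjusted over the list alone). In UPR regulators 4 of 8 were higher and 1 was lower (mean 0.61, adjusted p = 0.00303). CRT1B (AT1G09210, 1.79 ± 0.16), PDIL1-2 (1.41 ± 0.16), NAC103 (AT5G64060, 2.52 ± 0.52), SEC31A (2.76 ± 0.28) and BZIP60 (1.61 ± 0.13) were examples, CRT1B being a calreticulin and NAC103 a transcription factor of the UPR. In root hair 6 of 7 were higher (mean 2.80, adjusted p = 0.000188, 7 were higher adjusted over the list alone). The count was 472 with only these libraries fitted, 664 with a spread per group and 1169 without WT Tm 2.

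Between DTT and AZC 1808 genes differed, 978 higher with DTT and 830 lower. The heat shock genes HSP22 (at least 149-fold lower), HSP23.6 (-8.35 ± 0.37) and HSP101 (-5.75 ± 0.21) were lower with DTT. Among heat shock genes 22 of 24 were lower (mean -5.05, adjusted p = 8.5e-96, 23 were lower adjusted over the list alone). In sulfur assimilation 7 of 11 were lower (mean -1.66, adjusted p = 1.95e-08, 8 were lower adjusted over the list alone). In root markers 6 of 10 were lower (mean -2.23, adjusted p = 5.86e-06, 7 were lower adjusted over the list alone). ER genes were higher with DTT: in ER protein folding 14 of 21 were higher (mean 0.72, adjusted p = 9.2e-11). In UPR regulators 4 of 8 were higher (mean 0.89, adjusted p = 1.41e-06). Of the ER to Golgi transport genes 4 of 7 were higher (mean 1.38, adjusted p = 2.54e-10, 6 were higher adjusted over the list alone). Examples were PDIL2-3 (AT2G32920, 1.46 ± 0.14), BIP1 (0.90 ± 0.13), BZIP60 (1.73 ± 0.13) and NAC103 (2.55 ± 0.51). In ER-associated degradation 5 of 9 were higher (mean 0.64, adjusted p = 5.79e-05). In immune response 7 of 12 were higher (mean 1.41, adjusted p = 2.57e-05). Examples were CYP82C2 (79.2-fold higher, 21.5 to 660.1), GSTU3 (AT2G29470, 24.1-fold higher, 7.90 to 119.8), NHL10 (2.91 ± 0.29) and DMP1 (3.86 ± 0.29). The count was 1200 without WT AZC 1.

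73 genes rose with all 3 inducers, against 2.62 in independent lists. In 20 simulations of unchanged groups against the same controls 0 did. Those simulations held no changed gene, so they cannot show what shared controls add among genes that respond. They held 13 ER protein folding genes, among them BIP1, CNX1, PDIL1-2, ERDJ3B and the Hsp90 SHD (AT4G24190), 3 UPR regulators (TIN1, BI1 and BZIP60), and 49 genes of no list. 33 genes fell with all 3 (1.31 in independent lists). By pairs, 235 genes rose with both Tm and DTT (81.0 in independent lists), 94 with Tm and AZC (29.3) and 151 with DTT and AZC (30.3). The covariance of log2 fold changes across genes was 0.17, 0.105 and 0.2 for these pairs, against simulated means of 0.0652, 0.065 and 0.0643. The correlations were 0.323, 0.265 and 0.398, below the simulated 0.394, 0.401 and 0.496. Shared mock libraries, too few to split, may add to each overlap. The 73 became 48 with each comparison fitted alone.

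Tm against mock in bzip17/28 asked what the response keeps with bZIP17 and bZIP28 mutated. 1200 genes changed, 478 higher and 722 lower. BIP1 (3.13 ± 0.15, adjusted p = 6.75e-23), CNX1 (3.51 ± 0.15, adjusted p = 1.2e-23) and BZIP60 (2.89 ± 0.13, adjusted p = 2.14e-23) rose, BIP1 from 112 ± 1.37 to 986 ± 70.6 CPM (SD, n = 3). Among ER protein folding genes 14 of 21 rose (mean 1.52, adjusted p = 1.96e-48). In ER-associated degradation 6 of 9 rose (mean 1.23, adjusted p = 1.03e-18). In UPR regulators 4 of 8 rose (mean 1.95, adjusted p = 3.71e-28). In ER to Golgi transport 4 of 7 rose (mean 1.99, adjusted p = 2.75e-29). In translocation 5 of 13 rose (mean 0.90, adjusted p = 5.24e-08). Within N-glycosylation 3 of 9 rose (mean 0.89, adjusted p = 2.5e-06, 3 rose and 1 fell adjusted over the list alone). The largest rises were SAR1A (5.64 ± 0.31), AT4G21730 (5.54 ± 0.33), TIN1 (5.37 ± 0.27) and NAC103 (4.88 ± 0.32). Falls were led by PDF1.4 (-3.59 ± 0.36), AT3G16670 (-3.12 ± 0.27), AT2G43620 (-2.98 ± 0.48) and AT2G27420 (-2.85 ± 0.36). In root markers 3 of 10 fell (mean -0.87, adjusted p = 0.00172, 5 fell adjusted over the list alone). Examples were TIP2;3 (AT5G47450, -2.54 ± 0.32) and IRT1 (AT4G19690, -2.11 ± 0.47). The arabinogalactan genes FLA8 (AT2G45470, -1.49 ± 0.20) and FLA2 (AT4G12730, -0.97 ± 0.17) fell. Among secreted cell wall proteins 1 of 15 rose and 6 fell (mean -0.41, adjusted p = 0.00392 or 0.101 with an estimated correlation, 2 rose and 8 fell adjusted over the list alone). 175 of the 478 raised genes also rose in WT, which shares no library (41.4 in independent lists).

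Tm against mock in bzip28/60 asked the same with bZIP28 and bZIP60 mutated. 250 genes changed, 88 higher and 162 lower, and with library size alone 129 were higher and 117 lower. Within ER protein folding 2 of 21 rose and 1 fell (mean -0.08, adjusted p = 0.758), a list that camera did not call here. In UPR regulators 0 of 8 passed (mean -0.08, adjusted p = 0.709, 1 rose adjusted over the list alone). BIP1 (0.89 ± 0.14), CNX1 (0.72 ± 0.15), UTR1 (1.52 ± 0.22) and SEC61G2 (0.65 ± 0.12) rose and PDIL1-3 (AT3G54960, -1.41 ± 0.24) fell. The largest rises were outside the ER lists: the U-box ubiquitin ligase PUB54 (AT1G01680, 31.2-fold higher, 8.30 to 264), the membrane-binding BAP2 (AT2G45760, 3.86 ± 0.60), the zinc finger gene ZAT11 (AT2G37430, 3.11 ± 0.65) and AT1G21525 (3.66 ± 0.38). In oxidative and mitochondrial stress 2 of 11 rose (mean 0.67, adjusted p = 5.15e-06, 4 rose adjusted over the list alone). An example was ZAT12 (1.70 ± 0.21). The fraxetin hydroxylase CYP82C4 (AT4G31940, -4.03 ± 0.47) and AT3G16670 (-3.65 ± 0.27) fell. In root hair 2 of 7 fell (mean -1.20, adjusted p = 1.59e-06, 6 fell adjusted over the list alone). In root markers 2 of 10 fell (mean -0.86, adjusted p = 1.59e-06, 5 fell adjusted over the list alone). Examples were XTH13 (AT5G57540, -2.65 ± 0.56) and IRT1 (-2.53 ± 0.44). In photosynthesis 1 of 19 rose and 1 fell (mean -0.08, adjusted p = 0.0227 or 0.527 with an estimated correlation, adjusted p up to 0.057 without bzip28/60 mock 2 or 3 or bzip28/60 Tm 2), and with library size alone adjusted p = 0.0607. The count was 732 with only these libraries fitted, 530 with a spread per group, 158 without bzip28/60 mock 1 and 138, 165 and 163 without bzip28/60 Tm 1, 2 and 3, and 33 of the raised genes also rose in WT (7.62 in independent lists).

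Tm against mock in bzip17/60 asked it with bZIP17 and bZIP60 mutated. 322 genes changed, 108 higher and 214 lower, and with library size alone 138 were higher and 138 lower. BIP1 (2.91 ± 0.14, adjusted p = 7.34e-21), CNX1 (2.90 ± 0.15, adjusted p = 2.17e-20) and ERDJ3B (2.60 ± 0.15, adjusted p = 1.87e-18) rose. Of the ER protein folding genes 12 of 21 rose (mean 1.3, adjusted p = 2.05e-75, 14 rose adjusted over the list alone). In translocation 2 of 13 rose (mean 0.77, adjusted p = 4.36e-06, 4 rose adjusted over the list alone). In ER-associated degradation 3 of 9 rose (mean 0.36, adjusted p = 0.00126, 4 rose adjusted over the list alone). In UPR regulators 2 of 8 rose (mean 0.63, adjusted p = 2.47e-05). Of the N-glycosylation genes 3 of 9 rose (mean 0.86, adjusted p = 4e-09), a list whose median was -0.0077, opposite to its mean. Examples were UTR1 (3.98 ± 0.23), TIN1 (3.37 ± 0.34), BI1 (1.08 ± 0.13) and SEC61G2 (1.67 ± 0.13), and PUB54 (3.65 ± 0.53) of no list rose as well. BZIP60 itself had 0.28 ± 0.17 (adjusted p = 0.54). In root markers 4 of 10 fell (mean -1.04, adjusted p = 1.62e-07, 6 fell adjusted over the list alone). Within secreted cell wall proteins 4 of 15 fell (mean -0.29, adjusted p = 0.000412, 5 fell adjusted over the list alone). PHT1;1 (-1.39 ± 0.23), the peroxidase PRX52 (AT5G05340, -3.29 ± 0.68) and CYP82C4 (-2.92 ± 0.35) fell. The count was 180 without bzip17/60 Tm 3, and 65 of the raised genes also rose in WT (9.35 in independent lists).

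Tm against mock in s1p/s2p asked it with the proteases mutated. 372 genes changed, 188 higher and 184 lower. BIP1 (2.26 ± 0.14, adjusted p = 3.27e-17) and CNX1 (2.29 ± 0.15, adjusted p = 7.16e-17) rose. In ER protein folding 10 of 21 rose (mean 1.02, adjusted p = 6.21e-41, 14 rose adjusted over the list alone). In UPR regulators 4 of 8 rose (mean 1.69, adjusted p = 4e-32, 5 rose adjusted over the list alone). Among ER to Golgi transport genes 4 of 7 rose (mean 1.70, adjusted p = 1.69e-22). In ER-associated degradation 6 of 9 rose (mean 0.76, adjusted p = 3.47e-12). In translocation 4 of 13 rose (mean 0.61, adjusted p = 2.1e-06). SAR1A (95.8-fold higher, 26.2 to 796), TIN1 (4.42 ± 0.31), NAC103 (4.09 ± 0.45), AT4G21730 (4.22 ± 0.38), SEC31A (3.56 ± 0.20) and BZIP60 (2.12 ± 0.13) rose. In root markers 4 of 10 fell (mean -1.38, adjusted p = 1.87e-06, 6 fell adjusted over the list alone). IRT1 (-2.68 ± 0.50) and AT4G33720 (-5.48 ± 0.50) fell. 103 of the raised genes also rose in WT (16.3 in independent lists).

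Whether the Tm response itself differed from WT was tested as the difference of the 2 responses. Higher and lower refer to the signed log2 response, so a smaller fall is higher. The heat shock list and, by the preset correlation only, the glutathione transferases fell with Tm in WT, and both were called in no mutant, so their higher values below include that missing fall. In bzip28/60 426 genes differed, 220 with a lower and 206 with a higher response than WT, and with library size alone 269 were higher and 199 lower. ER genes were lower: BIP1 (-2.15 ± 0.20, adjusted p = 3.36e-11), CNX1 (-2.01 ± 0.21, adjusted p = 6.22e-10), PDIL1-1 (AT1G21750, -2.18 ± 0.21, adjusted p = 9.84e-11) and HRD3A (-1.89 ± 0.24, adjusted p = 3.22e-07) kept this under every alternative, as did SDF2 (AT2G25110, -1.73 ± 0.23), CRT1B (-2.96 ± 0.24), ERDJ3B (-2.60 ± 0.22) and PDIL1-2 (-3.15 ± 0.28). BZIP60 (-2.68 ± 0.21) was lower as a gene the genotype names. The UPR regulators list holds BZIP17, BZIP28 and BZIP60, and without these 3 its mean was -2.03 (adjusted p = 0.0066, up to 0.13 with 1 library left out). Among ER protein folding genes 14 of 21 were lower (mean -1.71, adjusted p = 3.04e-48). In ER-associated degradation 4 of 9 were lower (mean -0.91, adjusted p = 3.85e-08, 6 were lower adjusted over the list alone). In UPR regulators 1 of 8 was higher and 4 were lower (mean -1.62, adjusted p = 5.24e-06). Within ER to Golgi transport 3 of 7 were lower (mean -1.76, adjusted p = 2.73e-05, 4 were lower adjusted over the list alone). In N-glycosylation 3 of 9 were lower (mean -0.82, adjusted p = 7.2e-05, 4 were lower adjusted over the list alone). In translocation 4 of 13 were lower (mean -1.05, adjusted p = 0.000623, 5 were lower adjusted over the list alone). Examples were UTR1 (-1.51 ± 0.31) and SEC61G2 (-0.93 ± 0.17). TIN1 (-4.31 ± 0.83) and NAC103 (-5.10 ± 1.51) were lower, but single libraries decided TIN1 (adjusted p up to 0.0552 without bzip28/60 mock 1) and NAC103 (adjusted p up to 0.91 without bzip28/60 mock 1, bzip28/60 Tm 1, 2 or 3, WT mock 1 or 2 or WT Tm 2 or 3), and SAR1A was -4.09 ± 2.27 (adjusted p = 0.341). Within heat shock 10 of 24 were higher (mean 2.03, adjusted p = 1.01e-12, 14 were higher adjusted over the list alone). Examples were HSP90.1 (AT5G52640, 2.50 ± 0.50), HSP70-4 (2.05 ± 0.37) and HSP23.5 (2.28 ± 0.46). In glutathione transferases 4 of 12 were higher (mean 1.14, adjusted p = 0.000138). Among oxidative and mitochondrial stress genes 4 of 11 were higher (mean 0.94, adjusted p = 0.00032). Of 43 calls under the naming rule 21 were kept under every alternative, and the call was lost for NAC103 with only these libraries fitted or a spread per group or the replicate block and for HSP23.5 with a spread per group. The count was 118 with only these libraries fitted, 210 with a spread per group, 244 without bzip28/60 mock 1, 263 without bzip28/60 Tm 1, 281 without WT mock 1 and 1180 and 258 without WT Tm 1 and 2.

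In bzip17/60 the response of 390 genes differed from WT, 184 higher and 206 lower, and with library size alone 250 were higher and 150 lower. BZIP60 (-2.35 ± 0.21, adjusted p = 8.79e-11), named by the genotype, and SAR1B (-1.09 ± 0.20, adjusted p = 0.00151) were lower, as were SEC31A (-4.51 ± 0.94), ARFA1D (-4.31 ± 0.72) and PDIL2-3 (-1.26 ± 0.22). Of the ER to Golgi transport genes 3 of 7 were lower (mean -1.93, adjusted p = 3.24e-05, 5 were lower adjusted over the list alone). In ER-associated degradation 1 of 9 was lower (mean -0.53, adjusted p = 0.00197, 6 were lower adjusted over the list alone). In UPR regulators 1 of 8 was higher and 3 were lower (mean -0.91, adjusted p = 0.0093, adjusted p up to 0.125 without WT Tm 1), which was not called without the 3 bZIP genes (adjusted p = 0.452). Within ER protein folding 2 of 21 were lower (mean -0.32, adjusted p = 0.0465 or 0.294 with an estimated correlation, 4 were lower adjusted over the list alone, adjusted p up to 0.194 without bzip17/60 mock 1 or 2, bzip17/60 Tm 2, WT mock 2 or 3 or WT Tm 1). BIP1 (-0.13 ± 0.20), CNX1 (0.17 ± 0.20), SDF2 (0.02 ± 0.22), PDIL1-1 (-0.62 ± 0.21), HRD3A (-0.77 ± 0.25), TIN1 (-0.77 ± 0.54) and SAR1A (-5.68 ± 1.80) (adjusted p from 0.0626 to 0.976) did not pass. Of the heat shock genes 12 of 24 were higher (mean 1.74, adjusted p = 3.99e-11, 14 were higher adjusted over the list alone). Examples were HSP101 (2.06 ± 0.40) and HSP17.6B (AT2G29500, 2.92 ± 0.52). NAC103 (-4.53 ± 1.35) was lower. The call was lost for SEC31A (adjusted p up to 0.0742 without bzip17/60 mock 2) and NAC103 (adjusted p up to 0.166 without bzip17/60 mock 1, 2 or 3, bzip17/60 Tm 1, 2 or 3, WT mock 1 or 2 or WT Tm 2 or 3). Of 27 calls under the naming rule 2 were kept under every alternative, and the call was lost for SAR1B, SEC31A and PDIL2-3 with only these libraries fitted, for HSP101 with only these libraries fitted or a spread per group, for HSP17.6B with a spread per group, for NAC103 with only these libraries fitted or a spread per group or library size alone or the replicate block, for the UPR regulators list with no filter on low counts and for the ER protein folding list with only these libraries fitted or library size alone or single-model genes only. The count was 13 with only these libraries fitted, 101 with a spread per group, 194 and 208 without bzip17/60 mock 1 and 3, 151 without bzip17/60 Tm 3, 187 without WT mock 1 and 1173 and 140 without WT Tm 1 and 2.

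In bzip17/28 the response of 415 genes differed from WT, 195 higher and 220 lower. BI1 (1.19 ± 0.18, adjusted p = 1.57e-05) was higher and PDIL1-1 (-0.83 ± 0.21, adjusted p = 0.0118) lower, while BIP1 (0.09 ± 0.20), SDF2 (-0.68 ± 0.23), HRD3A (0.48 ± 0.23), NAC103 (0.94 ± 1.14), TIN1 (1.24 ± 0.45) and SAR1A (0.80 ± 1.1) (adjusted p from 0.0881 to 0.849) did not pass. CNX1 (0.78 ± 0.20, adjusted p = 0.0169) was higher, and the calls of CNX1 (adjusted p up to 0.103 without bzip17/28 mock 1, bzip17/28 Tm 3 or WT mock 1) and PDIL1-1 (adjusted p up to 0.0519 without bzip17/28 mock 1) were not kept. In UPR regulators 2 of 8 were higher (mean 0.41, adjusted p = 0.0103 or 0.0836 with an estimated correlation, 3 were higher adjusted over the list alone). In heat shock 5 of 24 were higher (mean 1.46, adjusted p = 2.18e-07 or 0.102 with an estimated correlation, 11 were higher adjusted over the list alone). In glutathione transferases 2 of 12 were higher (mean 1.15, adjusted p = 0.000589 or 0.102 with an estimated correlation, 5 were higher adjusted over the list alone). Of the ER protein folding genes 2 of 21 were higher and 3 were lower (mean -0.10, adjusted p = 0.789, 4 were higher and 4 were lower adjusted over the list alone). The lipoxygenase LOX4 (AT1G72520, 2.92 ± 0.63), HSP17.6B (2.11 ± 0.50) and ZAT12 (1.54 ± 0.29) were higher and TIP2;3 (-2.52 ± 0.48), AT3G22550 (-3.15 ± 0.76) and AT1G21525 (-2.72 ± 0.46) lower. Of 23 calls under the naming rule 5 were kept under every alternative, and the call was lost for PDIL1-1 and CNX1 with only these libraries fitted, for LOX4 with a spread per group and for HSP17.6B with either. The count was 140 with only these libraries fitted, 211 with a spread per group, 270 without bzip17/28 mock 1 or 2, 264 without bzip17/28 Tm 3 and 1078 without WT Tm 1.

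In s1p/s2p the response of 204 genes differed from WT, 122 higher and 82 lower. CRT1B (-2.25 ± 0.25, adjusted p = 4.88e-08) and PDIL1-1 (-1.49 ± 0.21, adjusted p = 3.28e-05) were lower. In ER protein folding 6 of 21 were lower (mean -0.61, adjusted p = 3.49e-08, 9 were lower adjusted over the list alone). BIP1 (-0.78 ± 0.20) and SDF2 (-1.0 ± 0.23) were lower in the full set, with calls lost for BIP1 (adjusted p up to 0.125 without s1p/s2p mock 2 or 3, s1p/s2p Tm 1 or 2, WT mock 2 or 3 or WT Tm 2) and SDF2 (adjusted p up to 0.0763 without s1p/s2p mock 2, s1p/s2p Tm 2 or WT mock 1). CNX1 (-0.44 ± 0.20), HRD3A (-0.16 ± 0.24), NAC103 (0.15 ± 1.59), TIN1 (0.29 ± 0.47), SAR1A (1.52 ± 1.2) and BZIP60 (-0.51 ± 0.18) (adjusted p from 0.12 to 0.977) did not pass. AT4G33720 (-3.70 ± 0.79) was lower. Among heat shock genes 5 of 24 were higher (mean 1.45, adjusted p = 1.1e-08 or 0.0632 with an estimated correlation, 15 were higher adjusted over the list alone). In glutathione transferases 2 of 12 were higher (mean 1.44, adjusted p = 1.51e-05 or 0.0557 with an estimated correlation, 5 were higher adjusted over the list alone). Of 20 calls under the naming rule 2 were kept under every alternative, and the call was lost for BIP1 and SDF2 with only these libraries fitted or a spread per group and for AT4G33720 with a spread per group. The count was 12 with only these libraries fitted, 316 with DESeq2, 361 with no filter on low counts, 28 with a spread per group, 99, 117 and 83 without s1p/s2p mock 1, 2 and 3, 76 and 67 without s1p/s2p Tm 1 and 2, 82 and 89 without WT mock 1 and 2 and 974 and 82 without WT Tm 1 and 2.

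**Figure D4:**
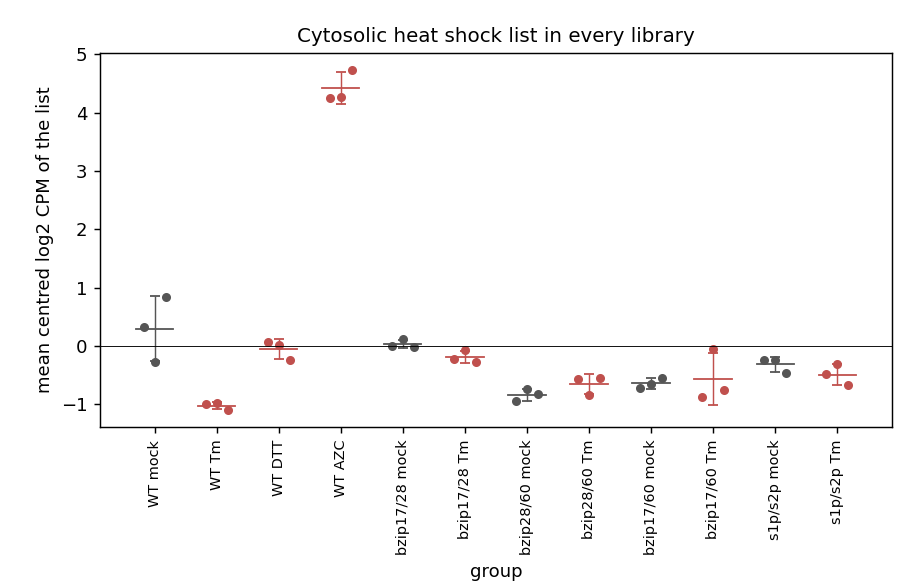
Mean centred log2 CPM of the measured heat shock genes (y axis) in the 36 libraries by group (x axis), with a point per library, a line at the mean and bars of 1 SD (n = 3). WT AZC stood at 4.42 ± 0.27, WT mock at 0.30 ± 0.55 and WT Tm at -1.02 ± 0.07.

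The mutant responses were also set against each other, without the WT libraries. Between bzip28/60 and bzip17/60, which share the bzip60 mutation by name, 30 genes differed, 25 with a lower response in bzip28/60. BIP1 (-2.02 ± 0.20, adjusted p = 4.87e-10), CNX1 (-2.18 ± 0.20, adjusted p = 1.86e-10), ERDJ3B (-2.69 ± 0.22, adjusted p = 2.98e-12) and UTR1 (-2.45 ± 0.34, adjusted p = 3.97e-06) were lower in bzip28/60, as were SDF2 (-1.75 ± 0.22), PDIL1-1 (-1.57 ± 0.21), PDIL2-2 (AT1G04980, -2.61 ± 0.31) and SEC61G2 (-1.02 ± 0.17). Among ER protein folding genes 12 of 21 were lower (mean -1.38, adjusted p = 3.31e-70). Among N-glycosylation genes 2 of 9 were lower (mean -0.82, adjusted p = 4.99e-09, 4 were lower adjusted over the list alone). In translocation 1 of 13 was lower (mean -0.65, adjusted p = 0.000732, 2 were lower adjusted over the list alone). In ER-associated degradation 2 of 9 were lower (mean -0.38, adjusted p = 0.00251, 3 were lower adjusted over the list alone). In UPR regulators 1 of 8 was lower (mean -0.71, adjusted p = 0.00355, 2 were lower adjusted over the list alone). TIN1 (-3.54 ± 0.85) and HRD3A (-1.13 ± 0.25) were lower too, with calls lost for TIN1 (adjusted p up to 0.487 without bzip17/60 mock 1 or 2, bzip17/60 Tm 1 or 3, bzip28/60 mock 1 or 3 or bzip28/60 Tm 1, 2 or 3) and HRD3A (adjusted p up to 0.138 without bzip17/60 mock 3, bzip17/60 Tm 3, bzip28/60 mock 1 or bzip28/60 Tm 2). NAC103 (-0.57 ± 1.50) and SAR1A (1.59 ± 1.81) (adjusted p from 0.939 to 0.981) did not pass. The call was lost for TIN1 with library size alone. The count was 69 with only these libraries fitted, 53 with DESeq2, 75 with no filter on low counts, 57 with a spread per group and 80 without bzip17/60 Tm 2.

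Between bzip28/60 and bzip17/28, which share the bzip28 mutation by name, 261 genes differed, 127 with a higher and 134 with a lower response in bzip28/60. CNX1 (-2.79 ± 0.21, adjusted p = 1.4e-14), BI1 (-2.56 ± 0.18, adjusted p = 3.04e-15), HRD3A (-2.38 ± 0.24, adjusted p = 1.04e-10) and, by genotype, BZIP60 (-2.94 ± 0.20, adjusted p = 3.04e-15) were lower, as were BIP1 (-2.25 ± 0.20), SDF2 (-1.05 ± 0.23), PDIL1-1 (-1.35 ± 0.21), PDIL2-2 (-3.99 ± 0.30) and TIN1 (-5.54 ± 0.88). Within ER protein folding 12 of 21 were lower (mean -1.60, adjusted p = 5.49e-56, 14 were lower adjusted over the list alone). In ER-associated degradation 6 of 9 were lower (mean -1.25, adjusted p = 1.8e-20). In UPR regulators 4 of 8 were lower (mean -2.02, adjusted p = 3.37e-15), with adjusted p = 1.79e-10 without the 3 bZIP genes. In translocation 3 of 13 were lower (mean -0.78, adjusted p = 2.79e-06). Within N-glycosylation 3 of 9 were lower (mean -0.85, adjusted p = 3.52e-07). In ER to Golgi transport 3 of 7 were lower (mean -1.84, adjusted p = 1.18e-06). NAC103 (-6.04 ± 1.44) was lower, a call lost (adjusted p up to 0.978 without bzip28/60 mock 1). SAR1A had -4.89 ± 2.32 (adjusted p = 0.386). PUB54 (3.93 ± 0.84) and RBCS1B (AT5G38430, 2.96 ± 0.69) were higher. The count was 683 with only these libraries fitted and 551 with a spread per group.

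Between s1p/s2p and bzip17/28, the proteases and their substrates, 70 genes differed, 37 with a higher and 33 with a lower response in s1p/s2p. CNX1 (-1.22 ± 0.20, adjusted p = 0.000282), BI1 (-1.05 ± 0.17, adjusted p = 0.000282) and SEC61G2 (-0.85 ± 0.17, adjusted p = 0.0048) were lower in s1p/s2p. Of the ER protein folding genes 5 of 21 were lower (mean -0.50, adjusted p = 3.63e-10, 9 were lower adjusted over the list alone). In ER-associated degradation 1 of 9 was lower (mean -0.47, adjusted p = 4.04e-05, 4 were lower adjusted over the list alone). Among ER to Golgi transport genes 1 of 7 was lower (mean -0.29, adjusted p = 0.00177, 2 were lower adjusted over the list alone). In UPR regulators 2 of 8 were lower (mean -0.26, adjusted p = 0.00656). BIP1 (-0.87 ± 0.20) and BZIP60 (-0.77 ± 0.17) were lower in the full set, with calls lost for BIP1 (adjusted p up to 0.0711 without bzip17/28 mock 1 or 2, bzip17/28 Tm 2, s1p/s2p mock 2 or s1p/s2p Tm 1 or 2) and BZIP60 (adjusted p up to 0.0995 without bzip17/28 mock 1 or 2, bzip17/28 Tm 1 or 3, s1p/s2p mock 1 or s1p/s2p Tm 1). SDF2 (-0.32 ± 0.24), PDIL1-1 (-0.66 ± 0.21), HRD3A (-0.64 ± 0.23), NAC103 (-0.80 ± 0.79), TIN1 (-0.95 ± 0.57) and SAR1A (0.72 ± 0.83) (adjusted p from 0.196 to 0.89) did not pass. AT1G21525 (2.98 ± 0.42) was higher, and AT4G33720 (-4.40 ± 0.65) and the gibberellin oxidase GA3OX1 (AT1G15550, -2.19 ± 0.44) lower. The count was 152 with only these libraries fitted, 119 with no filter on low counts, 124 with a spread per group and 41 and 45 without s1p/s2p Tm 1 and 2.

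Under mock, bzip17/28 differed from WT in 1856 genes, 941 higher and 915 lower, and with library size alone 1333 were higher and 626 lower. BZIP60 (0.95 ± 0.13, adjusted p = 6.45e-07) was higher, and BZIP28 (AT3G10800, 85.0-fold lower, 23.0 to 710.3) and BZIP17 (AT2G40950, -3.58 ± 0.62) were lower. The COPII gene SEC31A (3.89 ± 0.34), the ornithine acetyltransferase NATA1 (3.70 ± 0.54), the receptor-like gene RLP40 (AT3G24982, 3.62 ± 0.55) and AT5G59330 (12.9-fold higher, 3.34 to 111) were among the largest rises. In immune response 8 of 12 were higher (mean 1.2, adjusted p = 5.18e-05). Examples were WRKY70 (AT3G56400, 1.62 ± 0.23) and PDF1.2 (AT5G44420, 2.27 ± 0.46). In glutathione transferases 6 of 12 were higher (mean 0.90, adjusted p = 9.91e-05, 7 were higher adjusted over the list alone). Within oxidative and mitochondrial stress 6 of 11 were higher (mean 0.88, adjusted p = 0.000354). Examples were GSTU3 (2.53 ± 0.48) and CYP81D8 (1.66 ± 0.35). In auxin signalling and transport 6 of 11 were lower (mean -0.77, adjusted p = 0.000442). Of the secreted cell wall proteins 6 of 15 were lower (mean -0.54, adjusted p = 9.91e-05, 1 was higher and 9 were lower adjusted over the list alone), with the auxin efflux carrier PIN3 (AT1G70940, -0.95 ± 0.17) and IAA17 (AT1G04250, -0.74 ± 0.18) and XTH22 (AT5G57560, -1.07 ± 0.18). Within ER to Golgi transport 2 of 7 were higher (mean 0.81, adjusted p = 0.0168, 3 were higher adjusted over the list alone). In ER protein folding 4 of 21 were higher and 6 were lower (mean -0.05, adjusted p = 0.649, 6 were higher and 9 were lower adjusted over the list alone). The call was lost for the ER to Golgi transport list with only these libraries fitted or single-model genes only.

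In mock bzip28/60 528 genes differed from WT, 174 higher and 354 lower, and with library size alone 291 were higher and 268 lower. BZIP60 (-1.91 ± 0.15, adjusted p = 4.28e-13) and TIN1 (-2.54 ± 0.49, adjusted p = 0.000882) were lower. In UPR regulators 3 of 8 were lower (mean -0.75, adjusted p = 1.95e-05), which was not called without the 3 bZIP genes (adjusted p = 0.221). Within heat shock 12 of 24 were lower (mean -1.58, adjusted p = 1.06e-15, 14 were lower adjusted over the list alone). Examples were HSP70-4 (-1.92 ± 0.25) and HSP101 (-1.52 ± 0.25). The ribosomal protein gene RPL4D (AT5G02870, 1.06 ± 0.22) was higher, with reads shared with its paralog RPL4A. In cytosolic ribosome 3 of 8 were higher (mean 0.60, adjusted p = 2.88e-05, 4 were higher adjusted over the list alone). In root markers 2 of 10 were higher (mean 0.84, adjusted p = 9.91e-05, 7 were higher adjusted over the list alone). The spliceosomal RNA U6acat (AT5G40395, 2.72 ± 0.51) was higher. Among ER protein folding genes 0 of 21 passed (mean -0.10, adjusted p = 0.454). The count was 227, 285 and 245 without bzip28/60 mock 1, 2 and 3 and 201 without WT mock 1. The call was lost for the cytosolic ribosome list with single-model genes only.

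In mock bzip17/60 839 genes differed from WT, 357 higher and 482 lower. BZIP60 (-2.06 ± 0.15, adjusted p = 7.76e-14) was lower, as was BZIP17 (45.5-fold lower, 7.68 to 1845). In UPR regulators 3 of 8 were lower (mean -1.05, adjusted p = 0.00048), which was not called without the 3 bZIP genes (adjusted p = 0.65). The heat shock genes HSP17.6A (-4.26 ± 0.76), HSP70-4 (-1.26 ± 0.25) and HSP17.6II (AT5G12020, -2.86 ± 0.55) were lower. In the list 11 of 24 were lower (mean -1.32, adjusted p = 5.19e-08 or 0.168 with an estimated correlation, 14 were lower adjusted over the list alone). The phosphotransfer gene AHP4 (AT3G16360, 2.39 ± 0.54), CYP82C4 (2.68 ± 0.36) and the ribosomal gene RPL4A (AT3G09630, 1.64 ± 0.34) were higher. The count was 473 and 390 without bzip17/60 mock 1 and 2 and 443 and 427 without WT mock 1 and 3.

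In mock s1p/s2p 753 genes differed from WT, 296 higher and 457 lower, and with library size alone 468 were higher and 330 lower. BZIP60 (0.66 ± 0.13, adjusted p = 0.000971) was higher. The acid phosphatase gene PAP26 (AT5G34850, -7.48 ± 0.28, adjusted p = 3.31e-26) stood at 0.712 ± 0.394 CPM against 133 ± 15.8 CPM in WT mock (SD, n = 3), and PTAC18 (AT2G32180, -3.98 ± 0.33) and AT1G51440 (23.4-fold lower, 6.05 to 199.7) were lower as well. SEC31A (2.66 ± 0.40), AHP4 (2.48 ± 0.53), AT4G01390 (2.48 ± 0.46), APR1 (AT4G04610, 0.98 ± 0.20) and RPL4A (1.81 ± 0.34) were higher. Of the heat shock genes 5 of 24 were lower (mean -0.95, adjusted p = 0.000399 or 0.423 with an estimated correlation, 13 were lower adjusted over the list alone, adjusted p up to 0.054 without WT mock 3). Within ER protein folding 2 of 21 were higher and 2 were lower (mean 0.03, adjusted p = 0.894, 5 were higher and 5 were lower adjusted over the list alone). The count was 437 and 455 without s1p/s2p mock 2 and 3 and 429 without WT mock 1.

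Between mock s1p/s2p and mock bzip17/28 1045 genes differed, 432 higher in s1p/s2p and 613 lower. BZIP28 (94.8-fold higher, 25.8 to 789.9) and BZIP17 (3.72 ± 0.59) were higher in s1p/s2p, and BZIP60 had -0.29 ± 0.13 (adjusted p = 0.15). In immune response 6 of 12 were lower (mean -1.62, adjusted p = 2.24e-07, 9 were lower adjusted over the list alone), with the camalexin gene CYP71A13 (AT2G30770, 36.5-fold lower, 9.80 to 306), the flagellin-induced kinase FRK1 (AT2G19190, 12.6-fold lower, 4.04 to 63.3) and WRKY70 (-1.27 ± 0.22). In root hair 7 of 7 were lower (mean -2.15, adjusted p = 5.01e-09). In root markers 6 of 10 were lower (mean -0.93, adjusted p = 9.95e-06). Examples were RHS18 (AT5G22410, -3.34 ± 0.52) and PRP3 (-2.02 ± 0.38). In photosynthesis 1 of 19 was higher and 1 was lower (mean 0.10, adjusted p = 0.0178 or 0.254 with an estimated correlation, adjusted p up to 0.0878 without bzip17/28 mock 2 or 3 or s1p/s2p mock 2). In glutathione transferases 1 of 12 was higher and 4 were lower (mean -0.83, adjusted p = 0.000145, 1 was higher and 7 were lower adjusted over the list alone). In proline metabolism 2 of 3 were lower (mean -0.90, adjusted p = 0.00097, 3 were lower adjusted over the list alone). In secreted cell wall proteins 6 of 15 were higher (mean 0.59, adjusted p = 1.24e-06, 8 were higher adjusted over the list alone). Among auxin signalling and transport genes 3 of 11 were higher (mean 0.72, adjusted p = 0.000205). AT4G01390 (106-fold higher, 18.6 to 4240.1) was higher and PAP26 (-7.50 ± 0.28), RLP40 (53.2-fold lower, 14.4 to 444) and AT3G59930 (-5.42 ± 0.44) lower. The count was 1733 with only these libraries fitted, 1615 with a spread per group and 681 and 680 without s1p/s2p mock 2 and 3.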

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

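The tests of a stray library, of the heat shock level against the mutants and of the root genes, and the splits for Tm in WT and for bzip28/60 against WT, were chosen after the result was seen.

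The Tm response differed between genotypes by a direct test. The lists below were called with both correlations. Between bzip28/60 and WT 426 genes differed, and the mean log2 difference was -1.71 for ER protein folding, -0.91 for ER-associated degradation, -1.05 for translocation, -0.82 for N-glycosylation, -1.76 for ER to Golgi transport, -1.62 for UPR regulators, 2.03 for heat shock, 1.14 for glutathione transferases and 0.94 for oxidative stress. Between bzip17/60 and WT 390 genes differed, with -0.53 for ER-associated degradation, -1.93 for ER to Golgi transport, -0.91 for UPR regulators and 1.74 for heat shock. Between bzip17/28 and WT 415 differed, and between s1p/s2p and WT 204, with -0.61 for ER protein folding. Between bzip28/60 and bzip17/60 30 differed, with -1.38 for ER protein folding, -0.38 for ER-associated degradation, -0.65 for translocation, -0.82 for N-glycosylation and -0.71 for UPR regulators. Between bzip28/60 and bzip17/28 261 differed, with -1.60, -1.25, -0.78, -0.85 and -2.02 for the same 5 lists and -1.84 for ER to Golgi transport. Between s1p/s2p and bzip17/28 70 differed, with -0.50 for ER protein folding, -0.47 for ER-associated degradation, -0.29 for ER to Golgi transport and -0.26 for UPR regulators. That list holds the 3 bZIP genes. Without them (chosen after the result was seen) its adjusted p was 0.0066, 0.452, 0.00215, 1.79e-10 and 0.0238 in the order given. The call for bzip17/60 against WT was lost, as was the last with an estimated correlation (0.0645). For bzip17/28 against WT the list was called with both (mean 0.80, adjusted p = 0.000923 and 0.0142). Without WT Tm 1 the counts against WT became 1078, 1180, 1173 and 974 for bzip17/28, bzip28/60, bzip17/60 and s1p/s2p, and bzip17/60 lost UPR regulators (adjusted p = 0.125). The lowest were 264 without bzip17/28 Tm 3, 244 without bzip28/60 mock 1, 140 without WT Tm 2 and 67 without s1p/s2p Tm 2. Between bzip28/60 and bzip17/60 the count ran from 21 to 80 without bzip17/60 Tm 3 and 2, and between s1p/s2p and bzip17/28 it was 41 without s1p/s2p Tm 1. The share of reads set aside as ambiguous was above mock of the same genotype in all 3 libraries of 7 treated groups, at 42.1% in WT Tm, 41.5% in WT DTT, 41.0% in WT AZC, 42.2% in bzip17/28 Tm, 41.5% in bzip28/60 Tm, 41.1% in bzip17/60 Tm and 41.2% in s1p/s2p Tm.

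Other splits of the libraries were counted on fits of the comparison's own libraries. For the differences between Tm responses, with genotypes redrawn within each treatment, 7 of 100 splits gave as many genes as the real one for bzip17/28 against WT (140, highest other 1280), 8 for bzip28/60 (118 and 604), 10 for bzip17/60 (13 and 1302), 11 for s1p/s2p (12 and 999), 5 for bzip28/60 against bzip17/60 (69 and 579) and 8 for s1p/s2p against bzip17/28 (152 and 410). These splits also carry the genotype difference under mock, so for these counts they do not decide. Fewer reached the real count for bzip28/60 against bzip17/28, with 2 of 100 splits (683 and 892), and for the genes raised by all 3 inducers, with 3 of 100 (49 and 80, the 12 WT libraries fitted together). Most larger values came from splits that kept the Tm libraries of a genotype together and mixed or exchanged its mock libraries, which turns the difference between genotypes into a difference of responses. For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. Real and highest other counts were 262 and 0 for Tm, 1348 and 0 for DTT and 508 and 1 for AZC in WT, 811 and 1 for Tm against DTT, 472 and 0 for Tm against AZC and 1668 and 0 for DTT against AZC. For Tm in bzip17/28, bzip28/60, bzip17/60 and s1p/s2p they were 1674 and 0, 732 and 0, 322 and 3, and 450 and 1. Under mock they were 2202 and 0, 708 and 0, 841 and 0 and 748 and 0 for the same genotypes against WT, and 1733 and 0 for s1p/s2p against bzip17/28.

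The 3 WT Tm libraries varied more than those of any other group. A single stray library would leave 1 close pair, and the closest pair had a chi-square over its degrees of freedom of 8.95, above the highest of the other 11 groups (5.80). Lower depth is argued against by libraries thinned to the shallowest (coefficient of variation 28.1% against at most 13.9%). Without gene length and GC trends the median SD of log2 CPM was 0.388 against at most 0.258. Reads on no feature also varied most in WT Tm (SD 1.54 against at most 0.452%). Library, handling or dose differences may remain, and none was tested.

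The heat shock list fell with Tm in WT while it was called in no mutant, where its adjusted p was 0.29, 0.202, 0.627 and 0.23 for bzip17/28, bzip28/60, bzip17/60 and s1p/s2p. WT mock 3 alone is argued against, since without it the adjusted p was 6.13e-08. A raised level in WT mock may account for part of the fall: the list was higher on average in WT mock than in the mutant mocks (mean 1.13, 12 of 24 higher, camera p = 0.0115 with an estimated correlation), though WT mock 2 (-0.26) lay below the 3 bzip17/28 and 2 of the s1p/s2p mock libraries. The WT Tm libraries (-1.10 to -0.97) were below all 12 mutant Tm libraries (lowest -0.88), with camera p = 0.00738 with the preset and p = 0.247 with an estimated correlation, which leaves a fall specific to WT open. The mutations themselves and a batch of the WT libraries also stay open.

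Root hair or root marker genes fell with DTT, with AZC and with Tm in the mutants, with AZC the markers only by the preset correlation. A smaller share of root tissue, if lost evenly, would lower them all by 1 factor. Cochran's Q over the 17 root genes, divided by its degrees of freedom, was 4.13 for DTT, 7.39 for AZC and 4.88, 2.69, 2.32 and 2.22 for Tm in bzip17/28, bzip28/60, bzip17/60 and s1p/s2p, all above 1.64, the 0.05 bound of a chi-square approximation, which argues against a smaller share as the whole cause. With DTT the values ran from -5.72 (CASP2) to -0.87 (MYB36). A smaller share as part of the cause, an uneven loss of root tissue and transcriptional change in roots stay open and were not separated.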

How the results depend on the processing

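Of 13228 recomputed values of named genes 12276 kept their direction and their side of the threshold, 939 lost a call, 13 gained one and 0 reversed. Of 6857 list tests 195 lost and 100 gained a call. Uncalled values changed sign in 62 gene and 242 list tests. Counts of genes stayed within 1.5 times under other scalings, without organelle genes, with transcript models as deposited and with single-model genes. The last 2, and the spread per group, were chosen after seeing the data. The repeat number as a block kept all 22 counts within 1.5 times, with 14 of 755 named genes and 1 of 462 list tests losing a call. Samples shared only a number: same-number correlations over the 66 group pairs ran from -0.166 to 0.198 and were above 0.1 throughout in 0 pairs.

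Main counts stand in parentheses. With only the libraries of a comparison fitted the count became 732 for Tm in bzip28/60 (250), 262 for Tm in WT (1759), 1733 for mock s1p/s2p against bzip17/28 (1045), 472 for Tm against AZC (1919), 811 for Tm against DTT (2500), 140 for the response of bzip17/28 against WT (415), 13 for the response of bzip17/60 against WT (390), 683 for the response of bzip28/60 against bzip17/28 (261), 69 for the response of bzip28/60 against bzip17/60 (30), 118 for the response of bzip28/60 against WT (426), 152 for the response of s1p/s2p against bzip17/28 (70), 12 for the response of s1p/s2p against WT (204) and 48 for genes raised by all 3 inducers (73). With a spread per group the count became 530 for Tm in bzip28/60 (250), 535 for Tm in WT (1759), 1615 for mock s1p/s2p against bzip17/28 (1045), 664 for Tm against AZC (1919), 1084 for Tm against DTT (2500), 211 for the response of bzip17/28 against WT (415), 101 for the response of bzip17/60 against WT (390), 551 for the response of bzip28/60 against bzip17/28 (261), 57 for the response of bzip28/60 against bzip17/60 (30), 210 for the response of bzip28/60 against WT (426), 124 for the response of s1p/s2p against bzip17/28 (70) and 28 for the response of s1p/s2p against WT (204). With DESeq2 the count became 53 for the response of bzip28/60 against bzip17/60 (30) and 316 for the response of s1p/s2p against WT (204). With no filter on low counts the count became 75 for the response of bzip28/60 against bzip17/60 (30), 119 for the response of s1p/s2p against bzip17/28 (70) and 361 for the response of s1p/s2p against WT (204).

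With each library left out in turn the count ran from 368 to 528 for AZC in WT, 180 to 347 for Tm in bzip17/60, 138 to 188 for Tm in bzip28/60, 993 to 2421 for Tm in WT, 390 to 784 for mock bzip17/60 against WT, 201 to 398 for mock bzip28/60 against WT, 1200 to 1616 for DTT against AZC, 680 to 933 for mock s1p/s2p against bzip17/28, 429 to 612 for mock s1p/s2p against WT, 1169 to 2425 for Tm against AZC, 264 to 1078 for the response of bzip17/28 against WT, 140 to 1173 for the response of bzip17/60 against WT, 21 to 80 for the response of bzip28/60 against bzip17/60, 244 to 1180 for the response of bzip28/60 against WT, 41 to 73 for the response of s1p/s2p against bzip17/28 and 67 to 974 for the response of s1p/s2p against WT. Depth limits genes below about 5 CPM, and genes with several models are limited further by the reads set aside as ambiguous. The cause of these shifts was not tested. Fewer degrees of freedom do not explain the rises, and group spread ran from 5.57 to 28.2% (WT Tm).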

Other observations

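The genes of the next paragraph and its threshold of 8-fold were chosen after their values were seen.

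In some genes all 6 libraries of a genotype lay apart from all 30 others, with means at least 8-fold apart. In s1p/s2p these were lower: the acid phosphatase PAP26 at 1.29 ± 1.01 CPM against 119 ± 18.3 CPM (SD, n = 6 and 30), MUG8, whose locus tag lies next to that of PAP26, at 2 counts in all against 527, PTAC18 at 2.59 against 34.6 CPM and AT1G75945 at 2.53 against 33.0 CPM. In bzip17/28 the tyrosine aminotransferase TAT3 (AT2G24850) at 67.8 ± 15.8 against 3.67 ± 4.04 CPM and RLP40 at 12.5 against 0.58 CPM were higher, and AT5G37990 had 3 counts against 377, beside BZIP28. Among the 49 genes raised by all 3 inducers that no list holds, with log2 values for Tm, DTT and AZC, were AT3G51980 (3.41, 3.54 and 2.00), AT1G27330 (2.75, 2.56 and 1.71), the F-box gene FBS3 (AT4G05010, 3.07, 3.68 and 2.35) and the p24 cargo receptor p24delta5 (AT1G21900, 1.74, 2.22 and 1.48).

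A hypothesis set out before its test was that genes raised by Tm carry ER stress response elements (ERSE) in the 1000 bases upstream of the gene in TAIR10.1. Of 291 genes raised at least 2-fold in WT 289 were found in that annotation by locus tag, of which 20 had one (6.92%) against 22 of 1445 genes of like expression (odds ratio 4.80, 2.45 to 9.37, Fisher's exact p = 2.26e-06, adjusted over 4 tests 9.05e-06). Among them an ERSE stood in 14 of 103 genes raised less in bzip28/60 and 6 of the other 186 (odds ratio 4.69, 1.63 to 15.4, exact p = 0.0014, adjusted 0.00186). An ACGT-core element stood in 13 and 10 of the same genes (odds ratio 2.53, 0.983 to 6.73, exact p = 0.0400), an interval that includes 1. In 1 further test, without a prediction, it stood in 23 of 289 raised and 42 of 1445 matched genes (exact p = 0.000232). These values are consistent with ERSE as part of what sets the Tm response, while most raised genes held no such element, and both gene sets rest on the same WT libraries.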
